A study of Mus musculus with 6 samples.

How the data were processed

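CD45+ cells had been isolated from mouse hearts that received a sham procedure or 12 Gy in a single fraction, and were collected at 28 days. Per the labels' protocols, they were loaded on a 10x Genomics Chromium chip with the 3' version 3 chemistry, which tags each captured transcript near its 3' end with a cell barcode and a unique molecular identifier (UMI), and sequenced on an Illumina instrument. The deposited matrices hold raw UMI counts per gene and cell barcode, per the file headers. They were made with Cell Ranger 5.0.0 on the mm10 build, per the submitters' processing notes and the file headers. Those notes also name Seurat 3, whose role is not given in the sources used here. Each matrix lists 32285 genes, of which 32158 (99.6%) were placed on GRCm38 by the GENCODE vM21 annotation through their Ensembl identifiers. A 3' tag count does not see most of a transcript, so a deletion or a variant away from the tagged end can leave a gene's count unaltered, and genes with near-identical copies can share or lose UMIs.

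By title the 6 libraries were 2 sham (no genotype, taken as wild type), 2 irradiated C57Bl6J (wild type) and 2 irradiated C57Bl6J Tmem (STING knockout). No label gives a batch, date or animal. Cells were kept with at least 200 genes detected and at most 10% of UMIs from mitochondrial genes. Between 23.2% and 33.4% of the barcodes of a library exceeded that mitochondrial limit. Doublet scores came from scrublet as implemented in scanpy. Since its automatic threshold marked almost no barcodes, the cells with the highest scores were removed in each library at a rate of 0.8% for every 1000 cells, which took 98 to 321 cells per library. The kept cells numbered 4519 and 5910 in the sham libraries, 3394 and 6014 in the irradiated wild-type libraries, and 5578 and 5864 in the libraries labelled knockout. Their median depths were 4409 and 4590, 6353 and 5536, and 6788 and 6206.5 UMIs in that order, so sham cells were shallower. The 2 libraries of a group were not the same counts deposited again, as chi-square values per degree of freedom were 73.6, 43.6 and 35.0 for sham, irradiated wild type and the libraries labelled knockout, which does not show that they came from separate animals.

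Cells were clustered with scanpy on 2000 variable genes without immunoglobulin, T-cell receptor, ribosomal, mitochondrial and sex-linked genes, with 30 principal components, 15 neighbours and Leiden resolution 1, and without integration between libraries. A cluster took the name of the class whose markers had the highest mean log level, standardized over the clusters. At least 3 of those markers had to be detected, with a fold of 1.5 in 10% of the cluster's cells, and the 10 genes with the highest fold could not hold more markers of another class. A cluster whose median depth was under that of its libraries divided by 3, and with none of its markers among those 10 genes stayed unnamed. A cluster in which the markers of a second lineage reached, in the median, 0.5 of the detection rate in the cluster that detected each most was set aside as mixed, a threshold chosen after the clusters had been seen. Macrophage-like clusters were led by Ms4a7 and Lilra5 (cluster 0), Ccl8 and Cd209f (1), Ccl7 and Hmox1 (2), Tnf and Tnfsf9 (9) and Ifit3 and Ifit2 (29). The leading genes were Acod1 and Il1r2 (5) and Retnlg and Lcn2 (7) for neutrophil-like, Cd79a and Ly6d (13) for B cell-like, Gpihbp1 and Fabp4 (18), Cytl1 and Npr3 (17) and Mmrn1 and Nts (28) for endothelial-like, and Chil3 and Plac8 (22) and Cd300e and Ace (20) for monocyte-like cells. Other classes were led by Mki67 and Birc5 (cycling), Gzma and Prf1 (NK cell-like), Cd3g and Trbc2 (T cell-like), Cd209a and Ccl17 (dendritic cell-like), Dcn and Gsn (fibroblast-like), Rgs5 and Tagln (mural-like), Csf2 and Rora (type 2 innate lymphoid-like) and Hbb-bs and Hbb-bt (erythroid-like). Smaller clusters were mast cell or basophil-like (Cpa3), mesothelial-like (Upk3b) and Schwann-like (Apod, Kcna1). The cycling class is defined by the cell cycle and mixes lineages. The macrophage markers' detection ratio in it was 0.741.

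Counts were summed per library over all kept cells and over each class with at least 20 cells in every library. The sums were fitted for all 6 libraries with edgeR 4.0.16 in R 4.3.3, after its own filter on low counts and TMM normalization, and tested with the quasi-likelihood F test on 3 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 counted as a call. The comparisons were irradiated against sham wild type (radiation), irradiated libraries labelled knockout against irradiated wild type (genotype), and, in all cells and in macrophage-like cells, irradiated libraries labelled knockout against sham wild type. The 5 named classes with the most cells were tested as planned. Differences of an effect between macrophage-like and neutrophil-like cells were tested as a class by group interaction with library as a block. Shares of classes were tested with edgeR on cell numbers with the library's kept cells as offset, over 16 classes. CPM values in the text come from edgeR's cpm function, and log2 CPM carries a prior count of 2.

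A set of 22 gene lists and 8 lists of markers of other cell types was tested with limma's camera (version 3.58.1) at a preset correlation of 0.01, again with a correlation estimated from the residuals, and with fry. Adjustment ran over all lists and classes of a comparison, 159 tests for radiation and for genotype and 57 for the libraries labelled knockout against sham. The lists covered interferon-stimulated genes, the interferon-gamma response, MHC class I and class II presentation, cytosolic DNA sensing, NF-kB cytokines, chemokines, p53 targets, senescence and secretion, tissue-resident, monocyte-derived and lipid-associated macrophage genes, fibrosis-associated factors, complement and phagocytosis, cell cycle, oxidative phosphorylation, glycolysis and hypoxia, dissociation stress, T and NK cytotoxicity, naive lymphocytes, T cell checkpoints and sex-linked genes. The other cell types were cardiomyocyte, fibroblast, endothelial, mural, Schwann, erythroid, platelet and mesothelial. Schwann, platelet and mesothelial markers had fewer than 3 tested members in macrophage-like cells and were not tested there. In all cells, Schwann markers were called by camera for genotype (adjusted p = 0.0036, and adjusted p = 0.538 with an estimated correlation), with 0 members past the threshold over all genes, and platelet and mesothelial markers were not (adjusted p = 0.295 and 0.789). Adjusted over all lists, the smallest p with an estimated correlation was 0.0762 for radiation, 0.407 for genotype and 0.432 for the libraries labelled knockout against sham.

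Genes named in the text followed a rule. It took the STING gene, then, in each comparison, the 4 largest rises and falls over all cells, the 8 in the class with the most cells and the 2 in each other class. These came from genes with adjusted p under 0.05, a mean log2 CPM of at least 4 and every library of one group above every library of the other. Of each list it took up to 3 members with the smallest adjusted p under 0.05 in the class with the most cells, or the 2 most abundant where none passed. Genes named Gm with digits or ending in Rik, and ribosomal, mitochondrial, immunoglobulin, T-cell receptor and haemoglobin genes were left out of the rule, and sex-linked genes are given as a list. Some genes that met the rule are not reported here. The grouping, lists, markers, tests, rule and the alternatives not marked below as later were fixed before the data were examined.

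The edgeR gene, share and interaction tests, but not the list tests or DESeq2, were first run on simulated changes. With 200 genes changed in macrophage-like cells, the radiation test recovered 37.3%, 77.6% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold, with 13 false calls of 149, and the genotype test 44.8%, 77.6% and 98.5%, with 12 of 159. Over all cells the radiation test recovered 4.48%, 38.8% and 74.2%, with 11 false of 89, and the genotype test 2.99%, 40.3% and 78.8%, with 10 of 91. In endothelial-like cells these were 7.46%, 53.7% and 89.4% with 9 of 109 for radiation, and 13.4%, 67.2% and 93.9% with 14 of 130 for genotype. In monocyte-like cells they were 16.4%, 46.3% and 86.4% with 10 of 109, and 19.4%, 46.3% and 95.5% with 11 of 118. False calls exceeded the nominal 5% in these runs. The share test called a class tripled in size in 45 of 50 sets and 3 unchanged classes over all sets, and the interaction test recovered 49% of 200 genes with 1 false call of 99.

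Alternatives were DESeq2's size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, only the 4 libraries compared, each library left out in turn, doublets kept, mitochondrial limits of 5% and 20%, at least 500 genes per cell, Leiden resolutions 0.5 and 2, and for shares TMM on class numbers and classes by marker score. A fit that leaves a group with 1 library assumes that this library varies like the other groups. Alternatives chosen after seeing the data were 6 further classes, unnamed clusters added to the macrophage-like class, mixed clusters put back in their classes, and named immune cells as the denominator of shares. Python 3.11.15 was used with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Sequence reads were not analysed here.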

Results

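Leukocytes were profiled from mouse hearts 28 days after the heart had received either a sham procedure or a single 12 Gy dose from a small-animal irradiator. The cells had been sorted for CD45, the surface marker shared by leukocytes, and droplet libraries of messenger RNA 3' ends carrying unique molecular identifiers (UMIs) had been sequenced. The 6 libraries fell into 3 groups of 2: sham-treated wild type, irradiated wild type, and irradiated mice labelled as knockout for STING, the adaptor through which cytosolic DNA sensing induces type I interferon. The design asks how cardiac leukocytes differ after irradiation and whether that depends on STING. No sham-treated knockout library was analysed here, so a genotype difference without irradiation could not be measured. The deposited matrices held 45904 barcodes over 32285 genes. Total UMIs were 31650962 and 47017054 in the sham libraries, 32967187 and 58813701 in the irradiated wild-type libraries, and 59446833 and 59675213 in the libraries labelled knockout. After filtering, 31279 cells remained, between 3394 and 6014 per library, with median depths of 4409 to 6788 UMIs per cell. Nothing in the labels says that the 2 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot give a p below 0.333. Levels are CPM, counts scaled to a common total per library, over the kept cells of the class named, as mean ± SD with n = 2 libraries per group. Fold changes are log2 values from edgeR's quasi-likelihood fit ± their SE, with Benjamini-Hochberg adjusted p.

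The targeted gene was examined first as a check of the labels. The transcript of STING, Tmem173 (ENSMUSG00000024349), maps to chromosome 18, 35733679 to 35740554, minus strand, in GRCm38. Over all kept cells its level was 38.6 and 35.3 CPM in the sham libraries, 46.3 and 44.5 CPM in the irradiated wild-type libraries, and 37.8 and 41.5 CPM in the libraries labelled knockout. The log2 fold change of the libraries labelled knockout against irradiated wild type was -0.20 ± 0.09 (adjusted p = 0.388). In the macrophage-like class it was -0.27 ± 0.08 (adjusted p = 0.109). The transcript therefore did not separate the genotypes, and since the allele is not described in the labels, a 3' tag may lie outside the altered part and then checks nothing. The third group is called the libraries labelled STING knockout throughout, and every genotype direction rests on that label.

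The cells formed 31 clusters. Macrophage-like cells were the most numerous named class, with 10232 cells, followed by neutrophil-like (3779), B cell-like (3376), endothelial-like (2064) and monocyte-like cells (1886). Cycling, NK cell-like, T cell-like, dendritic cell-like, fibroblast-like and mural-like classes held 1282, 1104, 996, 678, 477 and 348 cells. Endothelial-like, fibroblast-like and mural-like cells were present although the sort was for CD45. Clusters carrying markers of more than 1 lineage were kept out of the classes. They took 12.7% ± 2.42 of sham cells, 13.5% ± 1.95 of irradiated wild-type cells and 9.58% ± 1.34 of cells labelled knockout (SD, n = 2). Clusters that met no class took 1.60% ± 0.160, 3.84% ± 0.00760 and 4.15% ± 1.25. Within the macrophage-like class, cluster 9 was led by Tnf, Tnfsf9 and Atf3 and cluster 29 by interferon-induced genes such as Ifit3 and Ifit2.

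Irradiated and sham wild-type hearts were first compared over all kept cells. Cd163, a scavenger receptor of tissue macrophages, fell from 175 ± 8.88 to 53.3 ± 6.45 CPM (log2 fold change -1.72 ± 0.11, adjusted p = 0.0376). Cd207, which encodes the lectin langerin, fell from 31.8 ± 0.365 to 13.8 ± 0.452 CPM (-1.20 ± 0.08, adjusted p = 0.0376). These were the 2 genes that fell among 15760 tested, and by edgeR 0 genes rose, while 3555 genes had an unadjusted p under 0.05. Of 52 interferon-stimulated genes, 0 passed over all genes and 41 rose when adjusted over the list alone (camera adjusted p = 8.14e-28, and adjusted p = 0.556 with an estimated correlation). The DESeq2 Wald test called 1077 genes and edgeR without a filter on low counts called 1078. Leaving out sham replicate 1 gave 85 genes, and leaving out any other single library gave 0.

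Irradiated and sham wild-type hearts were then compared within macrophage-like cells. Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), the transcription factor that amplifies interferon induction, rose from 44.3 ± 3.01 to 238 ± 36.6 CPM, a log2 fold change of 2.42 ± 0.20 (adjusted p = 0.000361). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), an interferon-induced chemokine, rose from 119.8 ± 22.6 to 455 ± 79.8 CPM (1.92 ± 0.18, adjusted p = 0.000675). Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), the chemokine receptor of inflammatory monocytes, rose from 87.0 ± 27.4 to 355 ± 46.7 CPM (2.03 ± 0.19, adjusted p = 0.00058). Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) fell from 429.6 ± 3.59 to 153 ± 33.4 CPM (-1.49 ± 0.13, adjusted p = 0.000431). In all, 596 genes rose and 477 fell of 12225 tested. By the rule for named genes, the largest rises were in Ly6a (3.27 ± 0.48), Kcnn4 (3.03 ± 0.17), Plac8 (3.02 ± 0.42), Ms4a4c (2.86 ± 0.21), Ccl5 (2.52 ± 0.43), Slfn1 (2.49 ± 0.23), Oas3 (2.43 ± 0.22) and Irf7. The largest falls were in Tcim (-2.42 ± 0.14), Ccn1 (-1.96 ± 0.37), Sgce (-1.80 ± 0.12), the metallothionein gene Mt2 (-1.77 ± 0.24), P3h2 (-1.74 ± 0.14), Ctla2a (-1.68 ± 0.31), the scavenger receptor gene Colec12 (-1.67 ± 0.16) and the urea transporter gene Slc14a1 (-1.61 ± 0.16). The adjusted p of these 16 genes lay between 5.83e-05 and 0.012. Irf7, Cxcl10, Ccr2 and Cd163 stayed called in each fit that left out 1 of the 6 libraries, as did 39 of the 68 named genes called in this comparison, and 0 named genes changed direction in those fits. Ly6a was not called without sham replicate 1 (3.15). The count was 358 without sham replicate 1, 665 without sham replicate 2, 545 without irradiated wild-type replicate 1, 79 with a mitochondrial share of at most 5%, 711 at Leiden resolution 0.5 and 1738 without a filter on low counts.

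**Figure D1:**
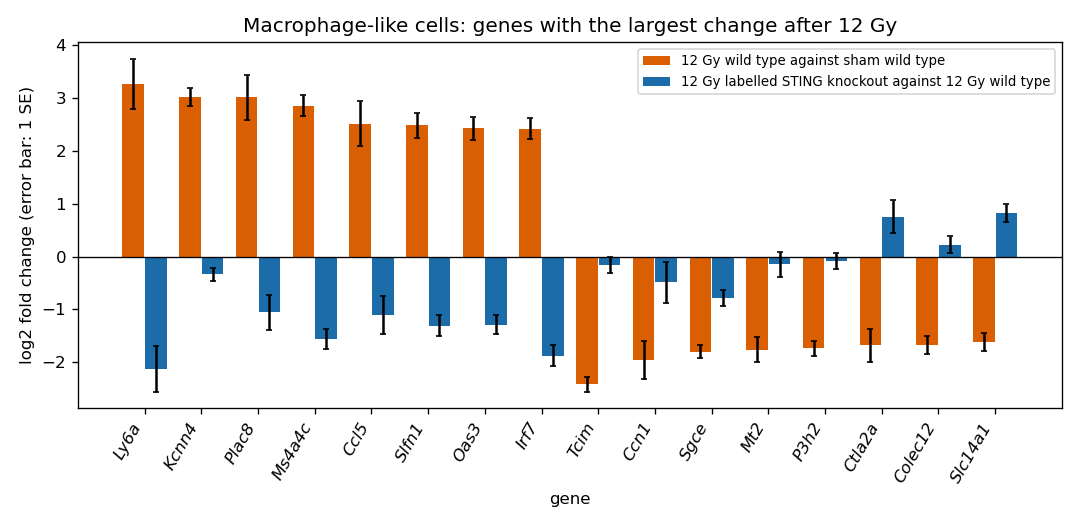
Log2 fold changes in macrophage-like cells (vertical axis, error bars 1 SE of the edgeR fit over 6 libraries) of the genes with the largest rises and falls after 12 Gy in wild type, with the same genes in the comparison of 12 Gy hearts labelled STING knockout with 12 Gy wild type. Irf7 rose by 2.42 in the first comparison and stood at -1.88 in the second, while Tcim stood at -2.42 in the first.

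Of 52 interferon-stimulated genes tested in irradiated macrophage-like cells, 48 rose, 0 fell and 4 did not pass, with 52 rising when adjusted over the list alone (camera adjusted p = 8.36e-76). Cluster 29, which these genes lead, held 1.16%, 10.1% and 4.52% of the macrophage-like cells of the sham, irradiated wild-type and knockout-labelled libraries, pooled per group. Within clusters 0, 1, 2 and 9, 11 of 51, 15 of 52, 10 of 48 and 38 of 52 interferon-stimulated genes rose, with list medians of 0.54, 0.64, 0.53 and 0.85. Ifi209, a member of the interferon-inducible nucleic acid sensor family, rose from 38.6 ± 1.80 to 84.5 ± 2.25 CPM (1.13 ± 0.11). Of 20 interferon-gamma response genes 9 rose (18 adjusted over the list alone), among them the Fc receptor gene Fcgr1 (0.90 ± 0.11) and the GTPase gene Irgm1 (1.03 ± 0.17). Of 20 MHC class I presentation genes 13 rose (19 adjusted over the list alone), including H2-K1 (0.75 ± 0.13), H2-D1 (0.52 ± 0.09) and the proteasome activator gene Psme2 (0.66 ± 0.11), whereas 1 of 11 MHC class II genes rose (2 adjusted over the list alone), H2-DMb2 (1.20 ± 0.25). Of 17 cytosolic DNA sensing genes 6 rose (8 adjusted over the list alone), among them the kinase gene Ikbke (1.74 ± 0.21) and Zbp1 (1.45 ± 0.23). Ifnb1, which encodes interferon beta, was among the 6, at 0.10 ± 0.00619, 3.32 ± 2.06 and 0.306 ± 0.0830 CPM in sham, irradiated wild-type and knockout-labelled libraries, too few UMIs for a stable fold. The camera adjusted p of these 4 lists were 1.55e-12, 1.98e-12, 0.00586 and 1.69e-05. With an estimated correlation the adjusted p rose to 0.483 for interferon-stimulated genes and 0.556, 0.556, 0.631 and 0.483 for the other lists in that order, so no list call held there.

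Of 28 p53 target genes in the same cells 12 rose and 0 fell (14 rose adjusted over the list alone), among them Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136), a p53-induced inhibitor of Akt, from 13.7 ± 1.55 to 50.1 ± 1.15 CPM (1.88 ± 0.10), the pro-apoptotic gene Bax (0.79 ± 0.08) and the stress cytokine gene Gdf15 (1.32 ± 0.16). Of 20 monocyte-derived genes 9 rose (11 adjusted over the list alone), including Ccr2, Ly6c2 (3.56 ± 0.42) and Gngt2 (0.90 ± 0.12). Of 27 tissue-resident macrophage genes 13 fell and 0 rose (15 fell and 1 rose adjusted over the list alone), including Cd163, the complement receptor gene Vsig4 (-1.57 ± 0.16) and the phosphatidylserine receptor gene Timd4 (-1.34 ± 0.14). Cluster 1, led by genes such as Lyve1 and Folr2 of the resident list, held 24.2% of sham and 13.1% of irradiated wild-type macrophage-like cells, pooled per group. Timd4 was at 0.05 with a mitochondrial share of at most 5%. Of 22 NF-kB cytokine genes 7 rose (10 rose and 1 fell adjusted over the list alone), such as the interleukin-1 receptor antagonist gene Il1rn (1.49 ± 0.21), Ccrl2 (0.70 ± 0.09) and Traf1 (0.83 ± 0.14). Of 22 chemokine genes 6 rose and 1 fell (12 and 3 adjusted over the list alone), with Ccl12 (1.47 ± 0.24) and Ccl4 (0.68 ± 0.10) beside Cxcl10. The camera adjusted p were 4.3e-11, 2.35e-11, 9.78e-13, 0.000164 and 3.51e-05 in that order. With an estimated correlation they were adjusted p = 0.367, 0.367, 0.484, 0.613 and 0.483.

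Among the remaining lists in irradiated macrophage-like cells, 8 of 35 cell cycle genes rose and 1 fell (18 and 1 adjusted over the list alone), including the replication licensing genes Mcm5 (0.99 ± 0.16) and Mcm6 (0.59 ± 0.10). Of 23 glycolysis and hypoxia genes 9 rose (11 rose and 1 fell adjusted over the list alone), with Mif (0.57 ± 0.08), Gapdh (0.48 ± 0.08) and Ldha (0.54 ± 0.09), and 3 of 48 oxidative phosphorylation genes rose (3 adjusted over the list alone). Of 8 T and NK cytotoxicity genes 4 rose (4 adjusted over the list alone), among them the chemokine genes Ccl4 and Ccl5. Camera called these 4 lists at adjusted p = 6.54e-09, 8.35e-06, 0.00156 and 0.000657, against adjusted p = 0.553, 0.556, 0.711 and 0.556 with an estimated correlation. Camera did not call the lists of complement and phagocytosis (2 of 27 rose and 7 fell, adjusted p = 0.172), lipid-associated macrophage genes (4 of 23 rose and 3 fell, 0.124), fibrosis-associated factors (3 of 25 rose and 3 fell, 0.444), senescence and secretion (5 of 22 rose and 2 fell, 0.164) or dissociation stress (1 of 25 rose and 2 fell, 0.385). Adjusted over the list alone, these 5 lists had 7, 8, 4, 6 and 1 members that rose and 8, 5, 4, 4 and 2 that fell. The complement factor gene Cfb went from 15.4 ± 3.29 to 74.5 ± 2.72 CPM (2.28 ± 0.16). Lgals3, which encodes galectin-3, rose by 0.96 and the apolipoprotein gene Apoe fell by 0.49 on the log2 scale. Spp1, which encodes osteopontin, rose by 0.90, but stood at -0.66 when unnamed clusters near the macrophages were added, an alternative chosen after seeing the data. The senescence list's Cdkn1a and Bcl2l1 rose by 0.64 and 0.50.

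Lists of other cell types were measured in the same class. Of 10 cardiomyocyte markers 2 fell, Ttn (-0.75 ± 0.15) and Myh6 (-0.52 ± 0.11), with 5 falling when adjusted over the list alone (camera adjusted p = 0.00269, and adjusted p = 0.6 with an estimated correlation), so heart muscle transcripts moved beside the gene groups above. None of 8 fibroblast, 11 endothelial, 5 mural and 5 erythroid markers passed over all genes or over the list alone, at camera adjusted p = 0.944, 0.705, 0.354 and 0.0681. Naive lymphocyte genes had 3 of 9 members that fell, Klf2 (-0.56 ± 0.11), S1pr1 (-0.41 ± 0.09) and Igfbp4 (-0.38 ± 0.09), and adjusted over the list alone 4 fell and 1 rose. That list's camera direction was down (adjusted p = 0.288) and its median -0.02, while its mean was 0.17. Of 8 T cell checkpoint genes and 5 sex-linked genes 0 passed over all genes or over the list alone (camera adjusted p = 0.322 and 0.346). The fibroblast list's median of 0.02 and mean of -0.03 differed in sign.

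In endothelial-like cells 302 genes were higher and 182 lower of 11212 after irradiation. Gdf15 (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456), a stress cytokine induced by p53, rose from 32 ± 8.48 to 693 ± 117 CPM (4.45 ± 0.20, adjusted p = 4.82e-05) and Nnmt, an enzyme that methylates nicotinamide, from 3.17 ± 0.675 to 37.3 ± 0.343 CPM (3.56 ± 0.32, adjusted p = 0.00291). Of 29 p53 target genes 18 rose and 0 fell (19 adjusted over the list alone), at a camera adjusted p = 2.28e-46 and an adjusted p = 0.0762 with an estimated correlation. Of 39 cell cycle genes 6 rose (23 adjusted over the list alone, camera adjusted p = 1.44e-15, and adjusted p = 0.483 with an estimated correlation). The matrix genes Dcn (-2.38 ± 0.30) and Prelp (-2.09 ± 0.38) fell. Dcn, a fibroblast marker, stood at 0.09 with doublets kept and at 1.90 at Leiden resolution 0.5, where Prelp stood at 0.01. In the same cells 3 of 8 fibroblast markers and 4 of 10 cardiomyocyte markers fell (3 and 10 adjusted over the lists alone, camera adjusted p = 0.0014 and 1.72e-09, with adjusted p = 0.556 and 0.484 with an estimated correlation). The endothelial count was 1718 without a filter on low counts, 67 with only the 4 libraries compared, 921 at Leiden resolution 0.5 and 295 with a mitochondrial share of at most 5%. It was 47 and 41 without sham replicates 1 and 2, 232 and 1369 without irradiated wild-type replicates 1 and 2, and 77 and 86 without knockout-labelled replicates 1 and 2.

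Monocyte-like, neutrophil-like and B cell-like cells had few genes past the threshold for radiation. In monocyte-like cells 4 rose and 3 fell of 8658. Retnla, a resistin-like gene of alternatively activated macrophages, rose from 9.42 ± 4.28 to 97.3 ± 35.1 CPM (3.32 ± 0.39, adjusted p = 0.0088), and Il1b, which encodes interleukin-1 beta, from 1309 ± 81.2 to 2454 ± 265 CPM (0.91 ± 0.12). Gpnmb (-3.49 ± 0.53) and the tetraspanin gene Cd63 (-1.58 ± 0.21) fell, though Cd63 stood at 0.29 with a mitochondrial share of at most 5%. The others, named after their values were seen, were Cd74 (0.69 ± 0.11), H2-Eb1 (0.79 ± 0.12) and Ctsd (-1.05 ± 0.17). In neutrophil-like cells 0 genes rose and Spp1 fell (-1.73 ± 0.21, adjusted p = 0.0194) among 6438 tested by edgeR, with 426 at an unadjusted p under 0.05. Clusters 5 and 7 held 286 and 72 of these cells in sham replicate 1, 297 and 759 in sham replicate 2, 127 and 63 in irradiated wild-type replicate 1 and 321 and 232 in replicate 2. In B cell-like cells 0 fell and Cxcl10 rose (4.71 ± 0.62, adjusted p = 0.0238), named after its value was seen, among 8856 tested by edgeR, with 953 at an unadjusted p under 0.05 and 11 calls by DESeq2. Interferon-stimulated genes were called up by camera in endothelial-like (3 of 47 rose, 8 over the list alone), monocyte-like (0 of 51, 7 over the list alone), neutrophil-like (0 of 47, 7 over the list alone) and B cell-like cells (1 of 41, 8 over the list alone), at adjusted p = 9.57e-06, 4.55e-20, 9.97e-09 and 8.19e-08. With an estimated correlation these were adjusted p = 0.695, 0.483, 0.556 and 0.483. The B cell-like count was 2 without sham replicate 1, 751 and 14 without irradiated wild-type replicates 1 and 2 and 175 without a filter on low counts, and the neutrophil-like count was 17 and 8 without sham replicates 1 and 2 and 0 without irradiated wild-type replicate 1 or either knockout-labelled library. The monocyte-like count was 0 and 15 without sham replicates 1 and 2, 14 and 51 without irradiated wild-type replicates 1 and 2, and 12 without either knockout-labelled library.

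**Figure D2:**
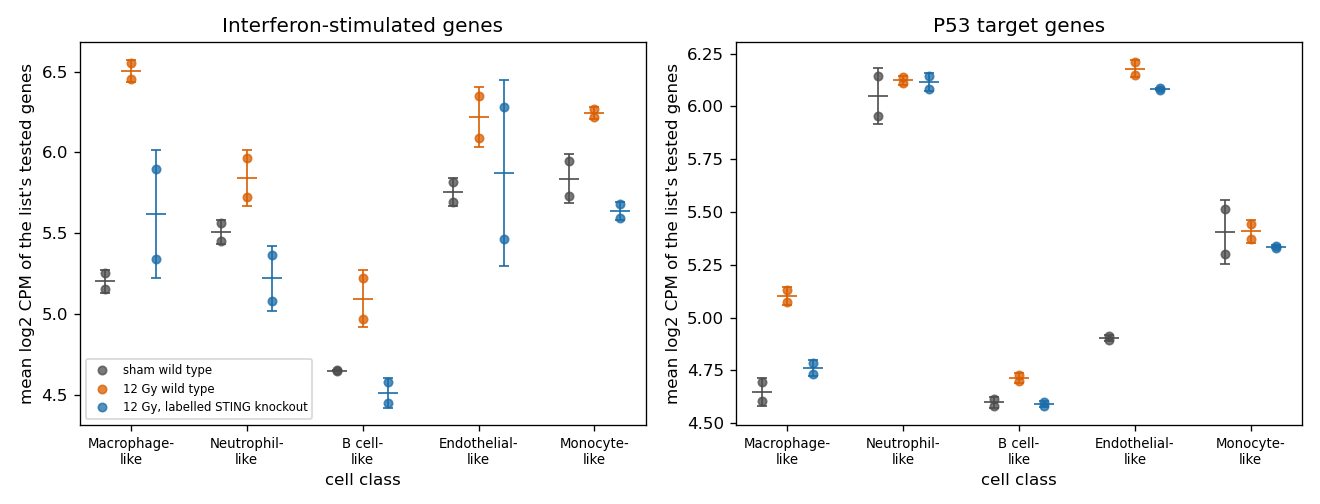
Mean log2 CPM over the tested members of 2 lists (vertical axis) in the 5 main classes (horizontal axis), with 1 point per library, and the mean with an error bar of 1 SD over the 2 libraries of each group. Interferon-stimulated genes in macrophage-like cells lie higher in both irradiated wild-type libraries than in the other 4, and p53 target genes in endothelial-like cells lie higher in all 4 irradiated libraries than in sham.

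Irradiated libraries labelled STING knockout were then compared with irradiated wild type in macrophage-like cells. Irf7 fell from 238 ± 36.6 to 64.7 ± 21.4 CPM (-1.88 ± 0.19, adjusted p = 0.00291) and Cxcl10 from 455 ± 79.8 to 137 ± 31.4 CPM (-1.73 ± 0.18, adjusted p = 0.00291), beside sham levels of 44.3 ± 3.01 and 119.8 ± 22.6 CPM. Tnf, which encodes tumour necrosis factor, fell from 318 ± 43.9 to 162 ± 4.95 CPM (-0.97 ± 0.10) and Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the p53-induced cell cycle inhibitor p21, from 719 ± 89.1 to 376 ± 14.2 CPM (-0.94 ± 0.10). Mrc1, the mannose receptor of resident macrophages, rose from 749.7 ± 36.5 to 1036 ± 24.1 CPM (0.47 ± 0.07, adjusted p = 0.0123). Of 12225 genes 182 were higher and 298 lower. The largest rises were in Ccdc152 (2.12 ± 0.16), the noncoding gene AY036118 (1.97 ± 0.13), the zinc transporter gene Slc39a1 (1.02 ± 0.10), Chp2 (0.83 ± 0.12), Slc14a1 (0.83 ± 0.17), Rasgrp3 (0.81 ± 0.14), Mir99ahg (0.80 ± 0.15) and Paip1 (0.78 ± 0.09). Among the largest falls were those of Ly6a (-2.13 ± 0.43), Irf7, H2-Q6 (-1.75 ± 0.37), Cxcl10, Oasl1 (-1.67 ± 0.22), Ms4a4c (-1.57 ± 0.19) and Ifit3 (-1.54 ± 0.24). Class I histocompatibility genes such as H2-Q6 have near-identical relatives, and AY036118 overlaps Gm42418 on the other strand, so their counts are uncertain. Irf7, Cxcl10, Tnf and Cdkn1a stayed called in each fit that left out 1 of the 6 libraries, whereas Mrc1 was not called without knockout-labelled replicate 1 (0.44) or 2 (0.49). The count of 480 was 234 without irradiated wild-type replicate 2, 60 and 161 without knockout-labelled replicates 1 and 2, 23 with a mitochondrial share of at most 5%, 200 at Leiden resolution 0.5, 213 with unnamed clusters added after seeing the data and 1154 without a filter on low counts. Of 55 named genes called, 21 stayed called in all 6 of those fits, and 0 changed direction.

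By list, 34 of 52 interferon-stimulated genes fell and 0 rose in macrophage-like cells of the libraries labelled knockout (49 fell adjusted over the list alone, camera adjusted p = 5.54e-52), including Isg20 (-1.32 ± 0.16). Of 22 NF-kB cytokine genes 9 fell (17 adjusted over the list alone), among them Tnf, Ccrl2 (-0.81 ± 0.09) and the interleukin-1 alpha gene Il1a (-1.51 ± 0.22). Of 22 chemokine genes 6 fell (12 fell and 1 rose adjusted over the list alone), including Ccl4 (-0.95 ± 0.10) and the monocyte attractant Ccl2 (-1.05 ± 0.15). Of 28 p53 target genes 9 fell (13 adjusted over the list alone), including Cdkn1a, Plk3 (-0.84 ± 0.09) and Phlda3 (-0.74 ± 0.09). Of 20 MHC class I genes 7 fell (13 adjusted over the list alone), with H2-K1 at -0.81 ± 0.13 and H2-D1 at -0.61 ± 0.09. Of 20 interferon-gamma response genes 3 fell (6 adjusted over the list alone), the signalling inhibitor gene Socs1 (-0.96 ± 0.10), Fcgr1 (-0.56 ± 0.11) and Irgm1 (-0.73 ± 0.16). Of 25 dissociation stress and immediate early genes 12 fell (23 adjusted over the list alone), such as Ier5 (-0.70 ± 0.09) and Atf3 (-0.52 ± 0.10), so this sign of handling moved beside the lists above. Camera adjusted p for the 6 lists after the first were 2.72e-15, 7.2e-08, 3.02e-09, 1.25e-10, 2.64e-08 and 2.32e-16. With an estimated correlation the adjusted p was 0.412 for the p53 list and 0.538 for the other 6.

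Among the remaining lists in the same comparison, senescence and secretion genes had 4 of 22 members that fell (6 adjusted over the list alone), MHC class II genes 1 of 11 (8), cytosolic DNA sensing genes 1 of 17 (4), T and NK cytotoxicity genes 1 of 8 (4), and fibrosis-associated factors 2 of 25 with 1 that rose (4 and 1), each number in parentheses being adjusted over the list alone. Camera adjusted p were 6.39e-07, 0.000198, 0.0313, 0.00128 and 0.0394, against adjusted p = 0.538 for the first 4 and 0.546 for the last with an estimated correlation. Of 27 tissue-resident macrophage genes 3 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.256), with F13a1 at 0.48 ± 0.09. The camera direction of that list was up, while its median was -0.03 and its mean -0.02. Monocyte-derived genes had 2 of 20 that fell, Ly6c2 (-1.91 ± 0.32) and Napsa (-0.84 ± 0.19), lipid-associated genes 1 that rose and 3 that fell of 23, and complement genes 3 and 3 of 27, with Cfb at -1.36 ± 0.15. Camera called none of these 3 (adjusted p = 0.128, 0.183 and 0.194), nor cell cycle (0 of 35 passed, 0.63), oxidative phosphorylation (2 of 48 fell, 0.162), glycolysis (0 of 23 passed, 0.153), naive lymphocyte (1 of 9 fell, 0.445), checkpoint (1 of 8 fell, 0.143) or sex-linked genes (1 of 5 rose and 1 fell, 0.984). Adjusted over the list alone, monocyte-derived genes had 5 that fell, lipid-associated genes 1 that rose and 4 that fell, complement genes 5 and 7, naive lymphocyte genes 3 that fell, oxidative phosphorylation genes 2 that fell, checkpoint genes 1 that fell and sex-linked genes 1 that rose and 1 that fell. Cardiomyocyte markers had 2 of 10 that fell, Myl2 (-0.42 ± 0.08) and Actc1 (-0.58 ± 0.12), and 1 that rose, Ttn (0.68 ± 0.14), with 9 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.000121, and adjusted p = 0.538 with an estimated correlation). Erythroid markers had 0 of 5 past the threshold over all genes and 5 that fell over the list alone (camera adjusted p = 0.000599, and adjusted p = 0.538 with an estimated correlation), the haemoglobin gene Hbb-bs standing at 103 ± 76.7, 44.6 ± 54.7 and 3.61 ± 0.650 CPM in sham, irradiated wild-type and knockout-labelled libraries. Fibroblast, endothelial and mural markers had 0 members past the threshold over all genes or over the list alone (camera adjusted p = 0.443, 0.386 and 0.997).

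Over all kept cells edgeR called 1 gene higher and 2 lower for genotype, with 2266 at an unadjusted p under 0.05 and 252 calls by DESeq2. AY036118 (ENSMUSG00000105361, chromosome 17, 39847113 to 39848035) rose from 34.5 ± 0.229 to 132 ± 20.3 CPM (1.93 ± 0.13, adjusted p = 0.0271). Named after their values were seen, Gm10076 (-2.44 ± 0.15) and G530011O06Rik (-2.44 ± 0.16) fell. Leaving out any of the 4 irradiated libraries gave 0 calls. In monocyte-like cells 15 genes were higher and 54 lower of 8658, with the siderophore-binding gene Lcn2 from 10.9 ± 4.94 to 37.0 ± 3.92 CPM (1.76 ± 0.30) and the chemokine gene Ccl7 from 106 ± 16.3 to 28.5 ± 25.9 CPM (-1.77 ± 0.37). Lcn2 was also among the 10 leading genes of neutrophil-like cluster 7, and neutrophil-like shares were 7.40% ± 2.54 and 14.2% ± 1.12 in these groups. Of 51 interferon-stimulated genes 10 fell there (28 adjusted over the list alone, camera adjusted p = 1.91e-34, and adjusted p = 0.407 with an estimated correlation). The monocyte-like count was 42 and 40 without sham replicates 1 and 2, 124 and 129 without irradiated wild-type replicates 1 and 2, and 8 and 23 without knockout-labelled replicates 1 and 2.

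In neutrophil-like cells 5 genes were higher and 13 lower of 6438, with Prok2, a secreted prokineticin, from 13.6 ± 11.0 to 104 ± 7.31 CPM (3.33 ± 0.37) and the antiviral gene Rsad2 from 279 ± 33.7 to 115 ± 8.68 CPM (-1.26 ± 0.18). The other 4 that rose, named after their values were seen, were AY036118 (2.42), Gm11713 (3.21), Steap4 (1.34) and Wfdc17 (1.60). Of the 13 that fell, 8 were encoded by the mitochondrial genome, from mt-Nd3 (-1.32 ± 0.17) to mt-Co2 (-0.84 ± 0.14), chosen after their values were seen. Cluster 7 held 53.6% of the neutrophil-like cells labelled knockout, against 39.7% in irradiated wild type. Prok2 was not called without irradiated wild-type replicate 2 (2.29), and Rsad2 was not called when any 1 of the 4 irradiated libraries was left out. B cell-like cells had 5 genes higher and 12 lower of 8856, among them Zfp407 (1.33 ± 0.23), AY036118 (1.54 ± 0.18) and the histone gene Hist1h2ap (-2.11 ± 0.35). Named after their values were seen, Aldh1a3, Gm42418 (1.12) and Kmt2d (1.10) were the others that rose. Endothelial-like cells had 2 higher and 1 lower, AY036118 (2.13 ± 0.13) and, named after their values were seen, Gm42418 (1.34 ± 0.11) and Gm10076 (-2.33 ± 0.11). Their Gdf15 was 607 ± 44.2 CPM beside 693 ± 117 in irradiated wild type. Interferon-stimulated genes were called down by camera in neutrophil-like (2 of 47 fell, 9 over the list alone), B cell-like (5 of 41, 10 over the list alone) and endothelial-like cells (0 of 47, 3 over the list alone), at adjusted p = 2.24e-18, 1.25e-10 and 4.23e-08, and with an estimated correlation at adjusted p = 0.538, 0.407 and 0.613. The endothelial call had an adjusted p of 0.616 with the direction turned when knockout-labelled replicate 1 was left out. Leaving out sham replicates 1 and 2, irradiated wild-type replicates 1 and 2 and knockout-labelled replicates 1 and 2 in turn gave neutrophil-like counts of 42, 36, 19, 3, 2 and 3 and B cell-like counts of 6, 6, 1278, 78, 4 and 3, and the endothelial-like count was 157 and 33 without irradiated wild-type replicates 1 and 2 and 2 without either knockout-labelled library.

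Irradiated libraries labelled knockout were also set against sham wild type, which differs in both genotype and treatment. In macrophage-like cells Ccr2 stood at 457 ± 45.5 CPM against 87.0 ± 27.4 (2.39 ± 0.19, adjusted p = 0.000195), Timd4 at 31.2 ± 4.44 against 121 ± 16.9 (-1.96 ± 0.14, adjusted p = 0.000131) and Cd163 at 139 ± 6.58 against 429.6 ± 3.59 (-1.63 ± 0.13, adjusted p = 0.000195). Of 12225 genes 354 were higher and 480 lower. Of 52 interferon-stimulated genes 7 rose (18 rose and 1 fell adjusted over the list alone), among them Isg15 (1.58 ± 0.23), of 27 tissue-resident genes 9 fell (10), of 20 monocyte-derived genes 5 rose (12), of 25 dissociation stress genes 16 fell (21), including Jun (-0.75 ± 0.09) and Fos (-0.70 ± 0.10), and of 10 cardiomyocyte markers 8 fell (9), the numbers in parentheses being adjusted over the list alone. Camera adjusted p were 9.08e-09, 1.06e-09, 2.62e-08, 1.32e-16 and 4.87e-12, against adjusted p = 0.673 for the first and 0.432 for the other 4 with an estimated correlation. Over all CD45+ cells 7 genes were higher and 17 lower, with Apln, which encodes the vascular peptide apelin, at a log2 fold change of 3.33 ± 0.34 and the cyclin gene Ccnd1 at 353 ± 33.2 against 105 ± 3.84 CPM (1.75 ± 0.19). The macrophage-like count was 182 without knockout-labelled replicate 2, 440 without knockout-labelled replicate 1, 458 and 362 without sham replicates 1 and 2, 140 with a mitochondrial share of at most 5% and 1565 without a filter on low counts. The count over all cells was 0 without sham replicate 2 or either knockout-labelled library, 6 without sham replicate 1 and 845 by DESeq2.

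Shares of cell classes were compared over all kept cells. Type 2 innate lymphoid-like cells, tissue lymphocytes that make interleukin-5 and interleukin-13, fell from 1.10% ± 0.261 of sham cells to 0.125% ± 0.0107 of irradiated wild-type cells (SD, n = 2 libraries per group, log2 ratio -3.08 ± 0.57, adjusted p = 3.23e-05 over 16 classes). Cycling cells rose from 2.13% ± 0.184 to 5.90% ± 0.0959 (1.47 ± 0.41, adjusted p = 0.00692) and stood at 4.41% ± 0.475 in the libraries labelled knockout. Dendritic cell-like cells were at 1.30% ± 0.409, 2.87% ± 0.0312 and 2.40% ± 0.966 in sham, irradiated wild-type and knockout-labelled libraries, and their radiation difference did not pass (1.14 ± 0.43, adjusted p = 0.0533), though it did without either knockout-labelled library (adjusted p = 0.0468). Macrophage-like cells took 36.0% ± 5.76, 32.6% ± 3.46 and 30.9% ± 0.191. Neutrophil-like cells took 12.9% ± 7.03, 7.40% ± 2.54 and 14.2% ± 1.12, and their genotype difference did not pass (0.94 ± 0.40, adjusted p = 0.184). For genotype 1 class was called, erythroid-like cells, from 0.186% ± 0.137 to 0.00896% ± 0.0127 (-4.20 ± 1.04, adjusted p = 0.00299), resting on 34 cells in all libraries and lost without irradiated wild-type replicate 2 (-3.02, adjusted p = 0.530) or knockout-labelled replicate 1 (-6.40, adjusted p = 0.143) or 2 (-3.34, adjusted p = 0.233). Shares are set by the CD45 sort and the filters as well as by the heart. The fall of type 2 innate lymphoid-like cells stood at -0.68 when each cell took the class of its highest marker score, without clusters (adjusted p = 0.297), and the rise of cycling cells did not pass, with an adjusted p up to 0.205, when any single sham or irradiated wild-type library was left out, at log2 ratios of 1.39 to 1.56.

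**Figure D3:**
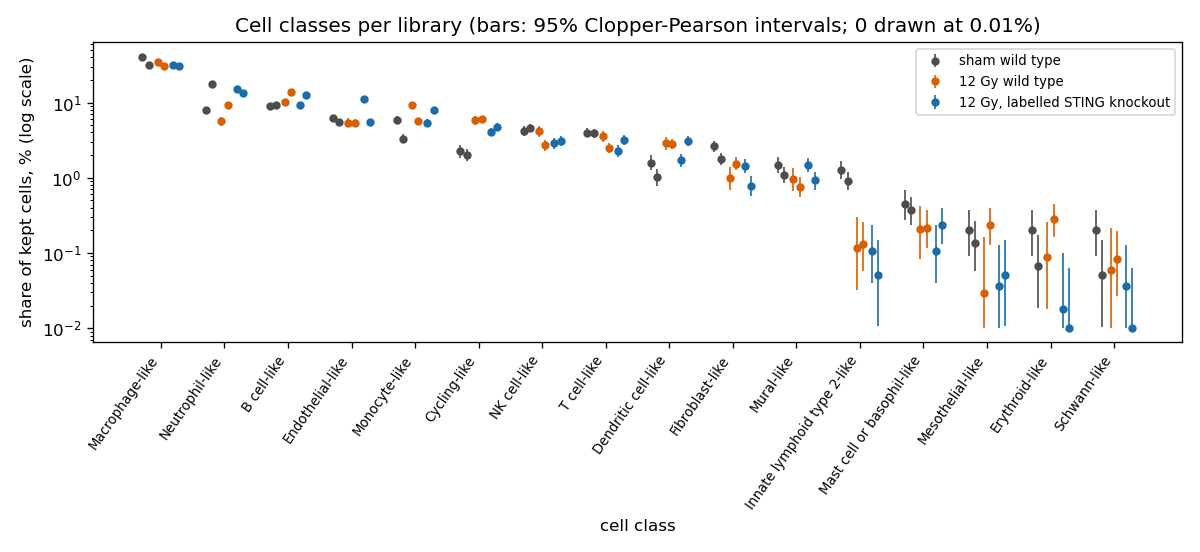
Share of kept cells in each of 16 classes (vertical axis, percent, log scale) per library, with exact Clopper-Pearson 95% intervals that cover counting error only; a share of 0 is drawn at the lower limit of the axis. Type 2 innate lymphoid-like cells lie higher in both sham libraries than in the 4 irradiated libraries.

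The radiation and genotype effects were compared across genes in macrophage-like cells. Of 596 genes that rose with irradiation 128 were called lower in the libraries labelled knockout, and of 477 that fell 63 were called higher. Independent lists would share 14.5 and 7.10 genes, leaving out the effect of the irradiated wild-type libraries in both comparisons. Across 12225 genes, which are not independent replicates, the correlation of the log2 fold changes was -0.445. With those libraries shared, 50 simulations of unchanged groups gave a mean of -0.534 (range -0.573 to -0.500) and 67.7% opposite signs over all genes, beside 68.7% observed. The covariance was -0.0822 against a simulated -0.0349, a difference of -0.0473. The 2 shared libraries were not split, so part of the overlap may come from them.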

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

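The tests of a handling batch, the counts in 6 added classes and the test of macrophage-like against endothelial-like cells were chosen only after the results had been seen. Effects on 160 of 12070 genes differed between macrophage-like and neutrophil-like cells for radiation, by the interaction of class and group in edgeR, and on 67 for genotype, with 1037 and 985 genes at an unadjusted p under 0.05. For radiation, 153 of these effects were higher in macrophage-like cells, such as those on the monocyte genes Plac8 (log2 fold changes of 3.02 against -0.37, adjusted p of the difference 2.85e-24) and Ly6c2 (3.56 against -0.56) and on Oas3 (2.43 against 0.06), which makes the second messenger of an antiviral nuclease. The fit pools the spread over genes, so a p this small does not rest on the 2 libraries per group alone. For genotype, 65 were higher in neutrophil-like cells, among them Ly6c2 (0.27 against -1.91), Cdkn1a (0.43 against -0.94) and Irf7 (-0.75 against -1.88). Leaving out knockout-labelled replicates 1 and 2 gave 99 and 98 genes for radiation, and leaving out sham replicates 1 and 2, irradiated wild-type replicates 1 and 2 and knockout-labelled replicates 1 and 2 in turn gave 121, 144, 150, 40, 17 and 26 for genotype. Between macrophage-like and endothelial-like cells the radiation effect differed on 233 of 13787 genes, with larger effects in endothelial-like cells on Gdf15 (4.45 against 1.32), on Ltc4s, which encodes leukotriene C4 synthase (2.96 against -0.22), and on Bax (2.01 against 0.79), and a larger effect in macrophage-like cells on the interferon-induced Ifit2 (2.29 against 0.60). The genotype effect differed there on 7 genes, such as Ifit2 (-1.26 in macrophage-like against -0.14 in endothelial-like cells, adjusted p of the difference 0.0458), and these tests were not refitted without single libraries.

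Interferon-stimulated genes were lower in the libraries labelled knockout than in irradiated wild type, with 34 of 52 that fell in macrophage-like and 5 of 41 in B cell-like cells, calls lost with an estimated correlation (adjusted p = 0.538 in the former). The values argue against a change in the mix of macrophage clusters, since within clusters 0, 1, 2 and 9, which had 0, 0, 0 and 1 interferon-stimulated genes among their 10 leading genes, the list's median log2 fold change was -0.49, -0.42, -0.53 and -0.77, and in each the knockout-labelled libraries both lay below both irradiated wild-type libraries in list mean, by -0.57, -0.54, -0.62 and -0.81 against pooled SDs of 0.183, 0.151, 0.138 and 0.152. Free macrophage RNA in the B cell droplets stays open, because over the 4 pairs of libraries the summed difference in B cell-like cells was 1.75, 0.849, 2.71 and 2.90 times what macrophage RNA would carry, and the bound set in advance was 2 in each pair. A handling batch that goes with the genotype label cannot be told apart from genotype, as no label gives a batch, 12 of 25 dissociation stress genes also fell in macrophage-like cells, and 24 genes shifted alike in 3 or more of 11 classes, 5 of them interferon-stimulated. Loss of STING signalling may explain the macrophage-like fall, a hypothesis inseparable here from such a batch or sex mix (Xist rose, Ddx3y fell).

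Of those 24 genes 19 have no place in the interferon list, against 9 genes in all that shifted alike in 3 or more classes with radiation. Gm10076 (chromosome 14, 105681828 to 105682211) was called lower in 11 classes with a median log2 fold change of -2.30, AY036118 higher in 9 (1.79) and Gm42418 (chromosome 17, 39846958 to 39848788), which overlaps it, higher in 8 (1.16). A strain variant carried along with the STING gene would place many of the 24 genes near it, yet 0% lay within 20 Mb of it, where 1.15% of the genes tested in macrophage-like cells lie. A handling batch that goes with the genotype label may account for some of the 19 genes, and variants elsewhere in the genome or the genotype itself could too. Nothing in the design tells these apart, and no biological explanation was tested.

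Tissue-resident macrophage genes were lower in irradiated wild-type macrophage-like cells, with 13 of 27 that fell. A change in the mix of macrophage clusters stays open, since the list's median within clusters 0, 1, 2 and 9 was -0.23, 0.024, 0.0072 and -0.26, which met neither bound set in advance, and these clusters held 34.4%, 24.2%, 16.7% and 23.5% of sham and 32.5%, 13.1%, 12.2% and 32% of irradiated wild-type macrophage-like cells, pooled per group. By edgeR 8 of 25 members fell and 0 rose within cluster 0, and 6 of 23 fell and 2 rose within cluster 9. The list mean also fell in B cell-like cells, so free RNA stays open. Monocyte-derived genes had positive medians in the same 4 clusters, at 0.63, 0.60, 0.48 and 0.31. Replacement of resident macrophages by cells of monocyte origin after irradiation may contribute, as a hypothesis that counts of RNA without a lineage label cannot test.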

How the results depend on the processing

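The settings with unnamed clusters added, mixed clusters put back and named immune cells as the denominator were chosen only after the results had been seen. With DESeq2's size factors in the edgeR fit every count of called genes stayed within 1.5 times its value, and over all cells and the 5 classes with the most cells the Leiden resolution of 2 and the minimum of 500 genes moved 1 count each, with 4 and 3 more moved in the 6 added classes. Among the single genes named, 4290 values under the alternatives set in advance kept direction and side of the threshold, 711 kept direction but no longer passed, 15 newly passed and 6 turned direction. Over all 375 list tests and all settings, later ones included, 5763 kept direction and side, 585 no longer passed, 276 newly passed and 50 turned. The fall of type 2 innate lymphoid-like cells held in each fit that left out 1 library (log2 ratio -3.31 to -2.82), and lists of interferon-stimulated genes in macrophage-like cells held their direction there, at adjusted p of 3.78e-134 to 5.69e-58 for radiation and 1.21e-127 to 2.28e-36 for genotype, although both calls were lost with an estimated correlation (adjusted p = 0.483 and 0.538) and with fry (0.179 and 0.231). Sums per library held 384519 to 3635552 counts in neutrophil-like and 8847561 to 15735222 in macrophage-like cells, and what depth limits was not tested, as NK cell-like sums of 398020 to 648421 counts gave 60 calls for genotype and endothelial-like sums of 1916858 to 6791166 gave 3. The causes of the changes below were not tested, apart from the fewer samples in fits without a library and the added genes in tests without a filter.

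Without a filter on low counts, counts of called genes for radiation, genotype and knockout-labelled against sham were 1078, 100 and 913 over all cells and 1738, 1154 and 1565 in macrophage-like cells, and for radiation and genotype 61 and 85 in neutrophil-like, 175 and 366 in B cell-like, 1718 and 371 in endothelial-like and 102 and 270 in monocyte-like cells. By the DESeq2 Wald test they were 1077, 252 and 845 over all cells, 29 for genotype in neutrophil-like, 11 and 53 in B cell-like, 49 for genotype in endothelial-like and 12 for radiation in monocyte-like cells, and 45 and 20 for the differences between macrophage-like and neutrophil-like effects. With only the 4 libraries compared, 0 genes for radiation and 15 for knockout-labelled against sham were called over all cells, 0 and 31 in neutrophil-like cells, 3 for genotype in B cell-like, 67 for radiation in endothelial-like and 39 for genotype in monocyte-like cells, and 100 and 139 effects differed between macrophage-like and neutrophil-like cells. With a mitochondrial share of at most 5%, counts were 0, 1 and 1 over all cells, 79, 23 and 140 in macrophage-like, 3 for radiation in neutrophil-like, 295 and 12 in endothelial-like and 0 and 29 in monocyte-like cells, and 97 and 36 for the differences. Timd4 (0.054) and Il1a (0.10, knockout-labelled against sham) in macrophage-like cells and Cd63 in monocyte-like cells (0.29) turned direction there. At most 20% gave 0, 6 and 83 over all cells, 2 and 34 in B cell-like, 7 for genotype in endothelial-like and 0 and 13 in monocyte-like cells. At least 500 genes per cell gave 0 for radiation in neutrophil-like cells, and Leiden resolution 2 gave 2 for radiation in B cell-like cells.

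At Leiden resolution 0.5 counts were 711 and 200 in macrophage-like, 0 for radiation in neutrophil-like, 0 and 7 in B cell-like, 921 and 16 in endothelial-like and 1 and 30 in monocyte-like cells. There Dcn (1.90) and Prelp (0.0065) turned in endothelial-like cells, and the erythroid-like share stood at -4.20 (adjusted p = 0.0728). With doublets kept, counts were 9 for knockout-labelled against sham over all cells, 0 for radiation in B cell-like and 7 for genotype in endothelial-like cells. Dcn stood at 0.086 there, the MHC class II list in neutrophil-like cells turned for genotype (adjusted p = 0.199), and the erythroid-like share was -3.08 (adjusted p = 0.413). With unnamed clusters added, 213 genes were called for genotype in macrophage-like cells and Spp1 stood at -0.66. With mixed clusters put back, counts were 49 and 415 in neutrophil-like 4 and 11 in B cell-like and 129 and 33 in T cell-like cells, the MHC class II list in neutrophil-like cells turned for radiation (adjusted p = 4.09e-08), and the erythroid-like share was -4.21 (adjusted p = 0.148). TMM on class numbers gave 1.29 for dendritic cell-like cells (adjusted p = 0.0308) and -4.14 for erythroid-like cells (adjusted p = 0.114), marker score classes -0.68 for type 2 innate lymphoid-like (adjusted p = 0.297) and -3.15 for erythroid-like cells (adjusted p = 0.576), and named immune cells as the denominator 1.17 for dendritic cell-like cells (adjusted p = 0.0109). Among genes with a mean log2 CPM of at least 5 the correlation of radiation and genotype effects was -0.512, beside a mean of -0.502 (range -0.568 to -0.450) in 50 simulations of unchanged groups.

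Over all settings that kept the 6 libraries or the 4 compared, counts for radiation and genotype in the added classes ranged from 0 to 464 and 3 to 385 in cycling, 1 to 69 and 14 to 176 in NK cell-like, 0 to 380 and 1 to 104 in T cell-like, 0 to 49 and 6 to 237 in dendritic cell-like, 1 to 116 and 5 to 148 in fibroblast-like and 3 to 100 and 10 to 226 in mural-like cells. Over the fits that left out 1 library, counts ranged from 0 to 85 for radiation, 0 to 2 for genotype and 0 to 17 for knockout-labelled against sham over all cells, and from 358 to 794, 60 to 480 and 182 to 987 in macrophage-like cells. For radiation and genotype they ranged from 0 to 17 and 2 to 42 in neutrophil-like, 1 to 751 and 3 to 1278 in B cell-like, 41 to 1369 and 2 to 157 in endothelial-like and 0 to 51 and 8 to 129 in monocyte-like cells, and from 98 to 214 and 17 to 150 for the differences between macrophage-like and neutrophil-like effects. Shares ranged from 1.39 to 1.56 for cycling, 0.85 to 1.49 for dendritic cell-like and -6.40 to -3.02 for erythroid-like cells (genotype). Some lists turned direction when the library named was left out, with adjusted p over these fits of 2.16e-07 to 0.840 for interferon-stimulated genes over all cells (knockout-labelled against sham; knockout-labelled replicate 2), 0.00327 to 0.693 for naive lymphocyte genes (radiation, irradiated wild-type replicate 1) and 1.43e-10 to 0.741 for the interferon-gamma response (knockout-labelled against sham, knockout-labelled replicate 2) in macrophage-like cells, 4.18e-16 to 0.596 for MHC class II (sham replicate 1) and 1.59e-08 to 0.512 for NF-kB cytokines (sham replicate 2) in neutrophil-like cells (radiation), 4.26e-19 to 0.711 for MHC class II, 6.31e-06 to 0.610 for NF-kB cytokines (both irradiated wild-type replicate 2), 3.66e-42 to 0.616 for interferon-stimulated genes and 4.68e-12 to 0.837 for the interferon-gamma response (both knockout-labelled replicate 1) in endothelial-like cells (genotype), and 1.85e-07 to 0.710 for the interferon-gamma response in monocyte-like cells (genotype, knockout-labelled replicate 1).

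The replicate numbers were not taken to pair the samples. Correlations of deviations between libraries with the same number were 0.0643, -0.0653 and 0.000735 in macrophage-like cells and -0.0617, 0.162 and 0.0173 over all cells. They were 0.0874, 0.0868 and 0.281 in B cell-like and 0.0604, 0.0669 and 0.0935 in cycling cells, positive but not all over 0.1. With the replicate block, counts were 0 and 1 for radiation and genotype over all cells, 3 for radiation in neutrophil-like, 111 and 463 in B cell-like, 13 for radiation in monocyte-like, 74 and 74 in cycling, 20 and 26 in fibroblast-like and 6 and 22 in T cell-like cells, 7 for radiation in NK cell-like and 10 for genotype in mural-like cells, and the other counts stayed within 1.5 times. With a mitochondrial share of at most 5%, B cell-like, fibroblast-like and mural-like cells were too few for a test. Some classes had no cluster and so no share, namely mesothelial-like cells with doublets kept, B cell-like, erythroid-like, fibroblast-like, mesothelial-like and Schwann-like cells at 5%, erythroid-like cells at 20% and with at least 500 genes, and type 2 innate lymphoid-like and mesothelial-like cells at Leiden resolution 0.5.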

Other observations

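The 6 classes, the lists picked for them and the genes named outside the naming rule in this part were chosen only after the data had been seen. In cycling cells, irradiation in wild type was followed by a rise of the interferon-induced Irf7 (2.44 ± 0.22, adjusted p = 0.00205) and Isg15 (1.99 ± 0.22) and by a fall of Cd163 from 180.4 ± 6.06 to 28.9 ± 8.91 CPM (-2.60 ± 0.22, adjusted p = 0.0018) and of the eotaxin gene Ccl24 (-1.71 ± 0.22), with 10 genes higher and 25 lower of 10954 by edgeR (log2 fold changes ± SE, levels as mean ± SD, n = 2 libraries per group). Of 52 interferon-stimulated genes 8 rose there (45 adjusted over the list alone, camera adjusted p = 1.83e-61, and adjusted p = 0.488 with an estimated correlation), and of 23 tissue-resident macrophage genes 7 fell (20 adjusted over the list alone, camera adjusted p = 2.01e-39, and adjusted p = 0.38 with an estimated correlation). In the libraries labelled knockout, against irradiated wild type, Ccl8 (1.78 ± 0.14), AY036118 (1.56 ± 0.17), Slc39a1 (1.13 ± 0.14) and Aldh1a3, a retinaldehyde dehydrogenase gene, rose and 7 genes fell, among them Irf7 (-1.64 ± 0.17), Rsad2 (-2.17 ± 0.25) and Hist1h2ap (-2.34 ± 0.25), while 41 of the 52 interferon-stimulated genes fell when adjusted over the list alone (2 over all genes, camera adjusted p = 1.45e-50, and adjusted p = 0.576 with an estimated correlation). Leaving out sham replicates 1 and 2, irradiated wild-type replicates 1 and 2 and knockout-labelled replicates 1 and 2 in turn gave 0, 0, 84, 121, 28 and 28 genes for radiation and 9, 9, 163, 66, 11 and 15 for genotype. In NK cell-like cells the MHC class II genes H2-Ab1 (1.84 ± 0.30), H2-Aa (1.61 ± 0.23) and H2-Eb1 (1.59 ± 0.26) and the immunoglobulin gene Iglc2 (2.22 ± 0.30) rose with irradiation and 0 genes fell of 6097 by edgeR, with 447 at an unadjusted p under 0.05 and 1 call by DESeq2. H2-Ab1 stood at 290.4 ± 84.7, 1030.4 ± 107 and 348 ± 210.3 CPM in sham, irradiated wild-type and knockout-labelled libraries. Of 8 MHC class II genes 3 fell for genotype (7 over the list alone, camera adjusted p = 1.2e-13, and 0.576 with an estimated correlation). For genotype 9 NK genes rose, among them Khdc1a (1.60 ± 0.31), and 51 fell. Among the latter were the B cell genes Igkc (-6.19 ± 1.02), Ighm (-4.13 ± 0.80), Iglc3 (-3.97 ± 0.70) and Iglc2 (-1.82 ± 0.29), and many ribosomal and mitochondrial genes such as Rpl35 (-0.84 ± 0.11) and mt-Nd3 (-0.91 ± 0.15). These 3 class II genes moved with Iglc2 in both comparisons, so B cell RNA in these droplets stays open. Aldh1a3 was at 0 in all 4 wild-type NK libraries and at 45.5 ± 5.66 CPM in the libraries labelled knockout. In the same order of libraries left out, the NK counts were 0, 0, 13, 11, 33 and 27 for radiation and 20, 24, 57, 67, 60 and 23 for genotype.

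In mural-like cells, the pericytes and smooth muscle cells of vessel walls, 7 genes rose with irradiation and 0 fell of 8708 by edgeR, with 764 at an unadjusted p under 0.05 and 11 calls by DESeq2. They included the p53 targets Gdf15 (2.98 ± 0.23, adjusted p = 2.56e-05), Bax (1.40 ± 0.22) and Phlda3 (1.29 ± 0.19), and Ltc4s (3.52 ± 0.43), which also rose in endothelial-like cells (2.96 ± 0.13). Of 24 p53 target genes 3 rose (8 adjusted over the list alone, camera adjusted p = 1.32e-19, and adjusted p = 0.277 with an estimated correlation). Nr1d1, a transcriptional repressor of the circadian clock, rose with irradiation (1.87 ± 0.19) and fell in the libraries labelled knockout (-1.18 ± 0.17), where 13 mural genes rose, among them the collagen gene Col1a1 (2.20 ± 0.35) together with other genes that fibroblasts express, Dpt (2.59 ± 0.48), Fmo2 (2.58 ± 0.48), Postn (1.46 ± 0.20) and Col6a1 (1.18 ± 0.21), and 11 fell, among them Ifit3 (-2.02 ± 0.33) and Zbtb16 (-2.22 ± 0.39). Of 9 fibroblast markers 2 rose there (3 adjusted over the list alone, camera adjusted p = 0.00338, and adjusted p = 0.594 with an estimated correlation). Leaving out sham replicates 1 and 2, irradiated wild-type replicates 1 and 2 and knockout-labelled replicates 1 and 2 in turn gave 2, 9, 17, 72, 11 and 11 mural genes for radiation and 24, 26, 90, 40, 7 and 23 for genotype. In T cell-like cells the cell cycle gene Stmn1 rose with irradiation (1.43 ± 0.23) and fell in the libraries labelled knockout (-1.12 ± 0.22), where 3 genes rose, AI504432 (1.95 ± 0.37), Rps27rt (1.53 ± 0.26) and Gm42418 (1.16 ± 0.17), and 8 fell, including the granzyme gene Gzmc (-3.62 ± 0.67). By edgeR 0 T cell genes fell with irradiation (529 at an unadjusted p under 0.05, and 0 by DESeq2), but this changed with the cells kept. With doublets kept 66 rose and 96 fell, at Leiden resolution 0.5 194 and 186, with mitochondrial shares of at most 5% and 20% 15 and 122 and 73 and 81, and with mixed clusters put back 59 and 70. In the same order of libraries left out the T cell counts were 0, 1, 0, 27, 10 and 12 for radiation and 9, 8, 16, 42, 7 and 23 for genotype. Dendritic cell-like cells had 0 genes past the threshold for radiation by edgeR (484 at an unadjusted p under 0.05, and 1 by DESeq2) and 7 for genotype, among them Aldh1a3 and AY036118, which were higher, and Il1b (-1.09 ± 0.15), Rrad, Gm10076 and the receptor component gene Ramp3 (-2.29 ± 0.34), which were lower, with counts of 0, 1, 0, 1, 0 and 0 for radiation and 8, 8, 1, 2, 13 and 21 for genotype in that order. In fibroblast-like cells the immunoglobulin gene Igkc rose with irradiation (2.67 ± 0.30) and fell in the libraries labelled knockout (-3.38 ± 0.34), where AY036118 (3.03 ± 0.31) and Gm42418 rose and 4 genes fell, among them Gm10076 and G530011O06Rik, with counts of 2, 2, 13, 58, 3 and 20 for radiation and 13, 13, 29, 55, 31 and 6 for genotype in that order. Of 42 interferon-stimulated genes in fibroblast-like cells 28 rose with irradiation and 14 fell in the libraries labelled knockout when adjusted over the list alone, with 0 over all genes (camera adjusted p = 9.07e-48 and 7.14e-23, and adjusted p = 0.488 and 0.576 with an estimated correlation).

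In monocyte-like cells 2 of 11 MHC class II genes rose with irradiation (5 adjusted over the list alone, camera adjusted p = 3.77e-09, and adjusted p = 0.484 with an estimated correlation) and 3 of 23 lipid-associated macrophage genes fell (9 adjusted over the list alone, camera adjusted p = 2.35e-11, and adjusted p = 0.484 with an estimated correlation). Each library carried both Xist and Y-linked transcripts over all cells, with Xist between 337 and 691 CPM and Ddx3y between 45.7 and 90.7 CPM. In macrophage-like cells Xist was 419 and 399 CPM in sham, 344 and 385 in irradiated wild type and 639 and 730.0 in the libraries labelled knockout, and Ddx3y was 47.8 and 44.1, 38.4 and 39.1, and 32.6 and 29.4 CPM. There Xist rose (0.79 ± 0.09, adjusted p = 0.0038) and Ddx3y fell (-0.45 ± 0.09, adjusted p = 0.032) in the libraries labelled knockout against irradiated wild type by edgeR. In the B cell-like cells of irradiated wild-type replicate 2, Ddx3y was 13.4 CPM and Eif2s3y 7.75 CPM, while the other libraries had at least 41.8 and 27.9 CPM.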
